A study of Mus musculus with 6 samples.

How the data were processed

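RNA from mouse colon lamina propria cells of 3 saline-treated (DSS) and 3 vesicle-treated (DSSFEV) animals was profiled, per the series design; the sample labels give the group and a number, not the animal. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected with oligo(dT) beads and libraries were made with a kit that does not mark strand. Reads from a gene and an overlapping antisense gene therefore cannot be told apart. Per the submitters' processing notes, cutadapt, TopHat2, HISAT2 and the mm10 build were used, with no versions or roles; the counting tool and annotation release are not given in the sources used here. The deposited table gives read counts per gene and, per the file headers, FPKM values for the same 6 libraries. The authors' FPKM equalled count divided by the table's gene length and library total. The table's coordinates matched GENCODE vM21 on GRCm38 for 2.29% of genes shared by identifier, so coordinates printed here come from vM21 by gene identifier, for 99.5% of identifiers. No gene in the table is an immunoglobulin or T cell receptor segment. One line of the table held no values and was not analysed here.

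The counts were filtered with edgeR's filterByExpr (minimum count 10, total 15), leaving 14040 of 21958 genes, and scaled with TMM. The 2 groups were compared with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, and p-values were adjusted with Benjamini-Hochberg at 0.05. Total counts per library ran from 13643508 to 17197651. The test was checked on simulated counts for the 14040 genes with known changes. With equal spread it recovered 30.1%, 88.1% and 96.7% of changes of 1.5, 2 and 4 fold, and with each group's observed spread 4.6%, 30.9% and 95.5%. Unchanged genes made up 5.44% and 3.3% of the calls in these 2 simulations. Genes and libraries were drawn independently. The check therefore does not cover libraries that repeat 1 sample or genes that move together.

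A total of 37 gene lists (metabolism, fibrosis, macrophage activation, cell type markers and handling) was fixed before the data were examined, along with the comparison, the tests and the naming rule. 35 lists with at least 5 tested genes were tested with camera in limma 3.58.1 (preset correlation 0.01) and again with an estimated correlation. Fry tested whether a list's genes move one way on balance, without comparison with other genes. 11 list genes had no row used here and were not analysed here. Genes were named if they were among the 10 largest rises or falls past the threshold with a mean log2 CPM of at least 1 and groups without overlap, or among 20 genes fixed in advance, or among up to 4 members with the smallest p of a list that was called or had at least 3 members past the threshold, or among the 3 most abundant in a group. Some genes that this rule takes are not reported here. The germinal centre list and the sets of fibroblast identity markers were written after the data were examined.

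Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, robust edgeR, no low-count filter, a filter of 50 counts in 3 libraries, removal of 13 mitochondrially encoded genes, a replicate block, leaving out each library, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fold threshold, and principal components of the 500 most variable genes. The DSS libraries summed as 1 library, thinning to 13636347 counts on tested genes and the pathway enrichment (hypergeometric, scipy 1.17.1) were chosen after seeing the data.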

Results

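The series profiled colonic lamina propria cells of mice with chronic colitis caused by dextran sulfate sodium (DSS), a colon irritant given to rodents. One group of 3 libraries (DSS) came from mice given saline, and the other group of 3 (DSSFEV) from mice given extracellular vesicles of Faecalibacterium prausnitzii, a butyrate-producing gut bacterium. The labels name the cells as lamina propria monocytes from mouse colon. Polyadenylated RNA was sequenced, and the number of reads per gene was used. The DSS libraries held 13643508, 14797699 and 15683120 counts, and the DSSFEV libraries 16300168, 14875931 and 17197651. Of 21958 genes, 14040 had enough reads to be tested. All values below are CPM (read counts scaled to a common library total) as mean ± SD with n = 3 libraries per group. Log2 fold changes are DSSFEV over DSS with the standard error, taken as their size over the square root of the quasi-likelihood F statistic. In the main fit that error pools both groups, which were unequal in spread.

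The comparison asks how vesicle treatment changed RNA levels in these cells, with fibrosis and macrophage metabolism as the subjects named by the series title. The libraries hold RNA of all cells in each preparation, so values of the metabolic lists need not describe macrophages. In the DSSFEV libraries 28 of 31 extracellular matrix genes, 14 of 18 macrophage and monocyte markers, 15 of 27 chemokines and 10 of 14 endothelial markers rose. Camera called these 4 lists with its preset correlation and none of them with an estimated one (adjusted p = 0.281, 0.354, 0.281 and 0.407 with an estimated correlation). Col1a1, the main fibrillar collagen chain, rose from 134 ± 1.59 to 415 ± 96.4 CPM, and Mrc1, the mannose receptor of macrophages, from 6.65 ± 0.14 to 33.0 ± 13.2 CPM. In the cholesterol synthesis list 6 of 21 genes fell, and in the tricarboxylic acid cycle list 3 of 21 (adjusted p = 0.407 and 0.508 with an estimated correlation). Idi1, an isoprenoid enzyme, fell from 213.6 ± 9.67 to 130.2 ± 24.6 CPM. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, 1516 genes differed, 1261 higher and 255 lower in DSSFEV. The 3 DSS libraries were nearly alike, and when they were summed and counted as 1 library, a fit chosen after seeing the data, 0 genes passed with edgeR, while 1093 had an unadjusted p under 0.05, 1034 of them higher. With no difference at all, a share of 0.05 of the 14040 tested genes would have an unadjusted p under 0.05. The fold changes could hardly move, as summing leaves the DSS mean almost as it was. Their median size over the 1516 genes was 1.240 log2 units before and 1.266 after. That of Col1a1 went from 1.63 ± 0.16 to 1.65 ± 0.31, of Mmp13 from 4.06 ± 0.28 to 4.07 ± 0.50 and of Rgs13 from -2.20 ± 0.20 to -2.17 ± 0.31. The calls ended because the error, taken from the DSSFEV libraries alone, grew 1.81 fold at the median and the residual degrees of freedom fell from 4 to 2. Leaving out a library moved the count to 89, 107 and 81 without DSS replicates 1, 2 and 3, and to 2523, 4122 and 430 without DSSFEV replicates 1, 2 and 3. Of 114 named genes past the threshold, 100, 98 and 100 were no longer called without DSS replicates 1, 2 and 3, and 58 without DSSFEV replicate 3. Over all genes losing the call without DSS replicates 1, 2 and 3, the median size of the log2 fold change was 1.204, 1.201 and 1.205 before and 1.212, 1.199 and 1.213 after, while the standard error grew 1.25, 1.26 and 1.26 fold at the median and the residual degrees of freedom fell from 4 to 3. With DSS libraries this alike, leaving out 1 could hardly move these folds, so only the error was open to change. Without DSSFEV replicate 3 the median size went from 1.121 to 1.066 and the error grew 1.14 fold.

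Of 31 tested genes in the extracellular matrix and fibrosis list, 28 rose, 0 fell and 3 did not pass, and 31 were higher when adjusted over the list alone. Their median log2 fold change was 1.35 (camera, preset correlation, adjusted p = 1.06e-35, and adjusted p = 0.281 with an estimated correlation). Camera asks whether a list moves more than other genes. Col1a1 lies on chromosome 11 at 94936224 to 94953042 (GRCm38), and its log2 fold change was 1.63 ± 0.16 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00463). Col3a1, which codes for another fibrillar collagen, rose from 365.0 ± 6.59 to 930.8 ± 197 CPM. Fn1, the gene of fibronectin, rose from 183 ± 7.16 to 448 ± 149 CPM, and Timp1, an inhibitor of matrix proteases, from 1.11 ± 0.27 to 4.31 ± 2.06 CPM. Biglycan (Bgn) and Timp2 rose by 1.58 ± 0.10 and 1.44 ± 0.09 log2 units. Acta2, the smooth muscle actin of myofibroblasts, measured 63.9 ± 4.28 and 76.8 ± 7.73 CPM and did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.111).

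In the TGF-beta signalling list, 9 of 21 genes rose and 0 fell (12 higher and 2 lower adjusted over the list alone), with a median of 0.36. The camera adjusted p was 7.37e-05, and adjusted p = 0.407 with an estimated correlation. Ltbp1 and Ltbp3, which bind latent TGF-beta in the matrix, rose by 1.07 ± 0.11 and 1.39 ± 0.18 log2 units, and the receptor gene Tgfbr2 by 0.59 ± 0.09. Tgfb1 itself measured 26.5 ± 2.23 and 52.8 ± 19.8 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0588). It passed with DESeq2 (Benjamini-Hochberg adjusted p = 0.00289) and, with edgeR's quasi-likelihood test, without DSSFEV replicate 1 (Benjamini-Hochberg adjusted p = 0.0438) or 2 (0.00351).

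**Figure D1:**
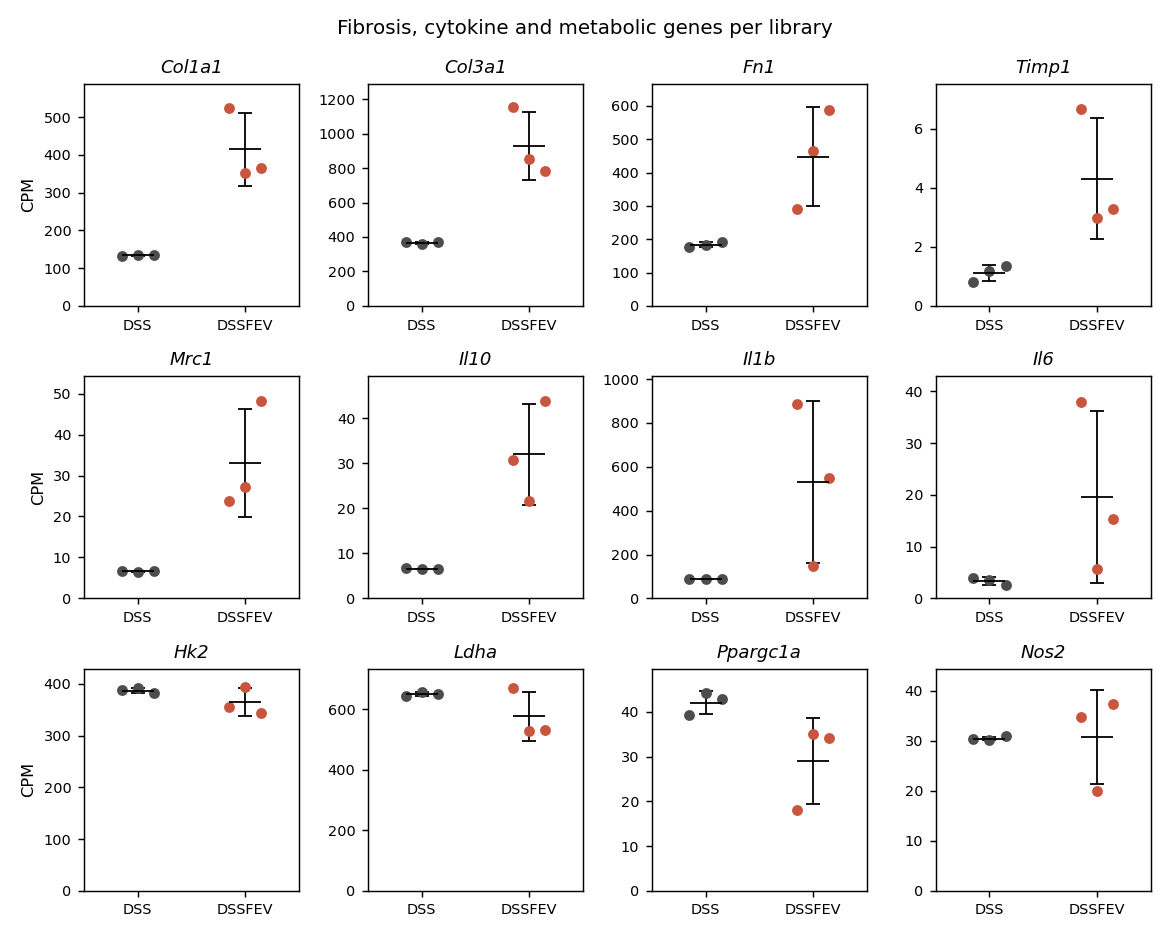
CPM (vertical axis) of 12 genes in the 3 DSS and 3 DSSFEV libraries; points are libraries, and the bars show the mean ± SD. Col1a1, Col3a1, Fn1, Timp1, Mrc1, Il10 and Il1b passed the test, and Il6, Hk2, Ldha, Ppargc1a and Nos2 did not.

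Macrophage and monocyte markers rose as a group. Of 18 genes, 14 rose and 0 fell (17 higher adjusted over the list alone), with a median of 2.67 (camera adjusted p = 3.1e-13, and adjusted p = 0.354 with an estimated correlation). The complement genes C1qb and C1qc went from 3.90 ± 0.19 to 40.7 ± 24.1 CPM and from 2.71 ± 0.37 to 31.3 ± 19.2 CPM. Adgre1, which codes for the macrophage antigen F4/80, went from 1.88 ± 0.44 to 22.6 ± 15.2 CPM. Without DSSFEV replicate 3 the log2 fold changes of C1qb, C1qc and Adgre1 went from 3.39, 3.53 and 3.59 to 2.79, 2.90 and 2.87. Both activation lists had medians above 0 but below that of the macrophage and monocyte markers. Whether more RNA of macrophages, or of other cells such as neutrophils, gave these rises was not tested, so they need not mean stronger activation. Neutrophil markers had medians relative to the DSS mean of 3.56, 0.91 and 2.88 in DSSFEV replicates 1, 2 and 3. Fn1 counts in both the M2-type list and the matrix list. Of 20 genes of alternative (M2-type) activation, 7 rose and 0 fell (15 higher adjusted over the list alone), with a median of 1.47 (camera adjusted p = 4.18e-08, and adjusted p = 0.281 with an estimated correlation). Stab1, a scavenger receptor, rose by 3.81 ± 0.39 log2 units, Il10, an anti-inflammatory cytokine, by 2.29 ± 0.26 and Igf1, a growth factor, by 2.37 ± 0.34. Of 22 genes of classical (M1-type) activation, 6 rose and 0 fell (17 higher adjusted over the list alone), with a median of 1.81 (camera adjusted p = 1.22e-06, and adjusted p = 0.508 with an estimated correlation). Fry gave this list an adjusted p of 0.151. Its medians relative to the DSS mean were 2.42, 0.55 and 1.52 in DSSFEV replicates 1, 2 and 3. Il1b, an inflammatory cytokine, went from 88.6 ± 1.53 to 529 ± 369 CPM, and Ptgs2, the inducible prostaglandin synthase, from 71.4 ± 1.26 to 343 ± 198 CPM. The log2 fold change of Il1b was 2.58, and 1.98 without DSSFEV replicate 1. Tnf, Il6, Nos2 and Arg1 did not pass. Tnf measured 43.5 ± 2.97 and 78.9 ± 23.4 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0544). Il6 measured 3.34 ± 0.70 and 19.6 ± 16.6 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0572), so both lie near the threshold. Nos2 measured 30.4 ± 0.39 and 30.7 ± 9.42 CPM, and Arg1 11.7 ± 1.34 and 32.9 ± 33.8 CPM.

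Of 27 chemokines, 15 rose and 0 fell (22 higher and 1 lower adjusted over the list alone), with a median of 2.34 (camera adjusted p = 2.05e-11, and adjusted p = 0.281 with an estimated correlation). Cxcl12, which retains leukocytes in tissue, went from 44.7 ± 1.16 to 138.3 ± 26.7 CPM, and Ccl11, an eosinophil attractant, from 6.41 ± 0.79 to 34.3 ± 13.1 CPM.

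The 4 lists of central metabolism had medians from -0.16 to -0.02. In the glycolysis list 2 of 20 genes rose and 1 fell (4 higher and 2 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.499). Its median was -0.06 and its mean 0.22, which differ in sign. Pfkfb3, which raises glycolytic flux, rose by 1.39 ± 0.27 log2 units and Eno2 by 0.97 ± 0.20, while Pgk1 fell by 0.30 ± 0.07. Hk2, Ldha and Slc2a1 measured 387.3 ± 5.50, 650.4 ± 7.91 and 160.6 ± 5.07 CPM in DSS and 365.0 ± 26.5, 577.7 ± 81.0 and 132.6 ± 19.3 CPM in DSSFEV, and did not pass. Pkm and Hif1a did not pass either. The tricarboxylic acid cycle list had 3 of 21 genes lower and 0 higher (6 lower adjusted over the list alone), with a median of -0.16 (camera adjusted p = 3.54e-05, and adjusted p = 0.508 with an estimated correlation). Idh3a, a subunit of isocitrate dehydrogenase, fell by 0.34 ± 0.06, Cs, citrate synthase, by 0.32 ± 0.07 and Dlat by 0.32 ± 0.07 log2 units. Among 60 nuclear genes of oxidative phosphorylation, 0 passed singly with edgeR (0 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 7.07e-05, and adjusted p = 0.672 with an estimated correlation). DSSFEV replicate 1 did not show this fall: medians relative to the DSS mean were 0.03, -0.15 and -0.24 in replicates 1, 2 and 3. Fatty acid oxidation had 1 gene higher and 1 lower of 23 (1 and 1 adjusted over the list alone) and was not called (camera adjusted p = 0.762), its median of -0.02 and mean of 0.02 differing in sign. Cpt1a, which admits fatty acids to mitochondria, measured 255.7 ± 7.29 and 257.8 ± 14.5 CPM. Ppargc1a, a regulator of mitochondrial biogenesis, measured 42.1 ± 2.58 and 29.1 ± 9.55 CPM and did not pass.

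Among genes fixed by size, the 10 with the largest rise were Il12b, Cemip, Mmp13, Retnlg, Hp, Il1a, Lcn2, Saa3, Mmp3 and Flt4. Mmp13, a collagenase at chromosome 9, 7272514 to 7283331 (GRCm38), rose from 3.02 ± 0.45 to 50.4 ± 15.8 CPM, a log2 fold change of 4.06 ± 0.28 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0022). Mmp3, another matrix protease, measured 100.1, 23.8 and 10.9 CPM in DSSFEV replicates 1, 2 and 3 against 3.11 ± 0.74 in DSS. Lcn2, an antimicrobial protein that binds siderophores, rose by 3.98 ± 0.74 log2 units and Saa3, an acute-phase gene, by 3.93 ± 0.84. Without DSSFEV replicate 1 the log2 fold change was 2.54 for Saa3, 2.48 for Mmp3, 3.42 for Cemip, 3.25 for Hp, 3.35 for Lcn2 and 3.12 for Flt4, against 3.93, 3.86, 4.63, 4.03, 3.98 and 3.82 with it, and without DSSFEV replicate 3 it was 3.41 for Retnlg, against 4.04. Il12b, a cytokine subunit, had 5 reads over the DSS libraries and 205 over the DSSFEV libraries, a ratio per read of 37.4 (exact 95% interval 15.8 to 116, counting error only). DSS replicates 1, 2 and 3 held 3, 1 and 1 of these reads and DSSFEV replicates 89, 10 and 106, and the log2 fold change of 5.03 became 5.76, no longer called, without DSS replicate 1.

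The largest falls included Prol1, Slc28a2b, Rgs13, Mybl1, Mef2b, Slpi, Gcsam, Fam221a and Efhb. Rgs13, Mybl1, Mef2b and Gcsam are known from germinal centre B cells. Rgs13, at chromosome 1, 144138654 to 144177372 (GRCm38), fell from 6.54 ± 0.83 to 1.42 ± 0.19 CPM, a log2 fold change of -2.20 ± 0.20 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00413). Mybl1 fell from 27.6 ± 0.97 to 7.63 ± 1.92 CPM, and Slpi, a protease inhibitor of mucosal surfaces, from 157.3 ± 4.40 to 55.0 ± 14.3 CPM. Prol1 measured 26.0 ± 2.94 CPM in DSS and 0, 0 and 2.95 CPM in DSSFEV replicates 1, 2 and 3.

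**Figure D2:**
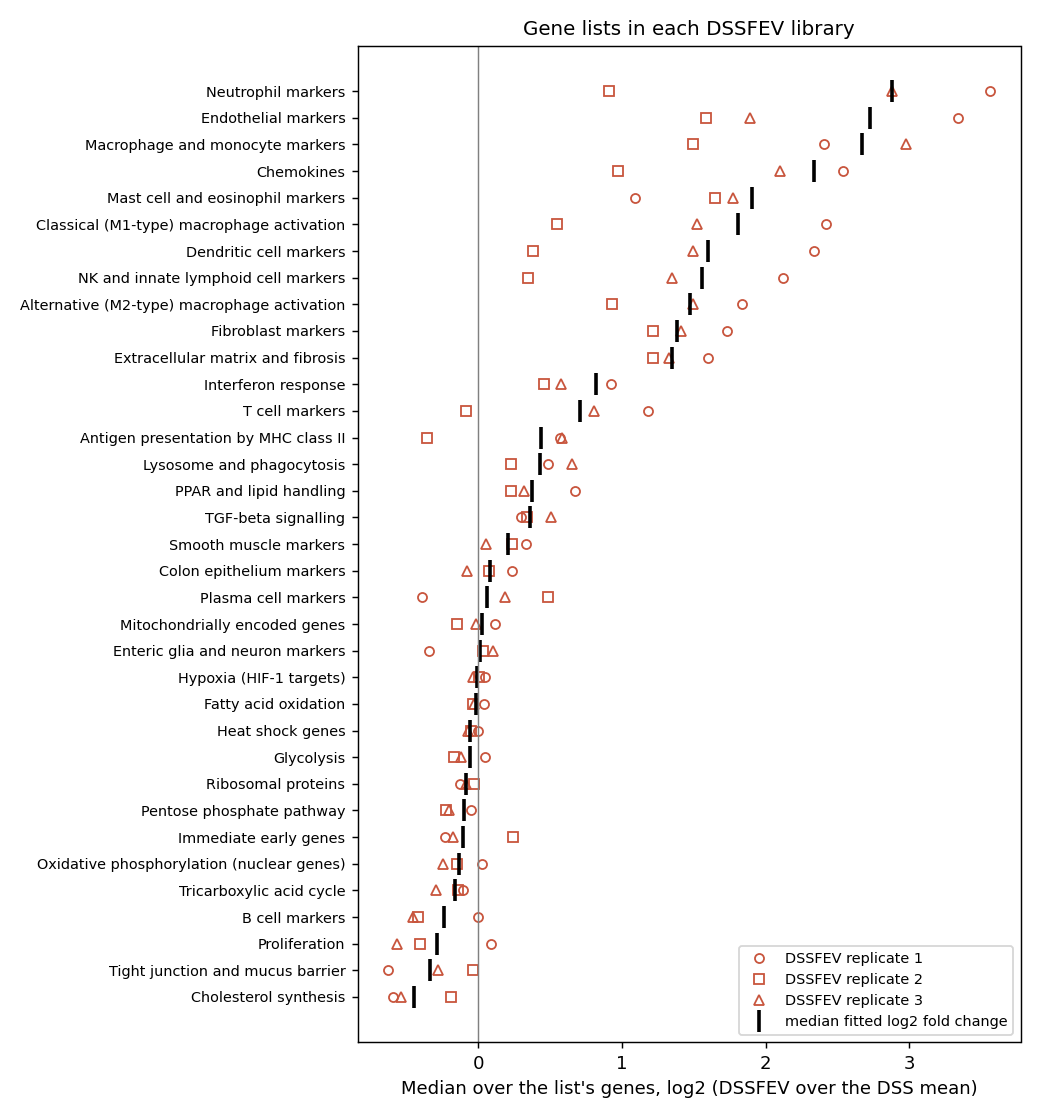
Median over each of 35 gene lists of log2 CPM in DSSFEV replicates 1, 2 and 3 (circles, squares, triangles) relative to the DSS mean, on the horizontal axis in log2 units, with the median fitted fold change as a black bar. Extracellular matrix genes lie at 1.60, 1.21 and 1.33 in the 3 libraries, and replicate 2 is lowest for most immune cell lists.

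Marker genes of cell types were measured alongside. Colon epithelium markers summed to 34850 ± 182 CPM in DSS and 30940 ± 4963 CPM in DSSFEV, against 266 ± 3.84 and 900 ± 369 CPM for macrophage and monocyte markers, sums over different genes. Muc2, the mucin of goblet cells and one of the most abundant genes, measured 11763 ± 168 and 10242 ± 3083 CPM. In the epithelium list 3 genes rose and 2 fell of 24 (3 and 3 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.87); Chga and Chgb, of enteroendocrine cells, rose, and Vil1 and Krt19 fell. Fibroblast markers had 9 of 13 genes higher (11 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 4.4e-15, and adjusted p = 0.281 with an estimated correlation). Endothelial markers had 10 of 14 higher (14 adjusted over the list alone), with a median of 2.73 (camera adjusted p = 1.85e-08, and adjusted p = 0.407 with an estimated correlation). Neutrophil markers had 6 of 12 higher (7 adjusted over the list alone), with a median of 2.88 (adjusted p = 0.413 with an estimated correlation), and mast cell and eosinophil markers 7 of 12 (8 adjusted over the list alone), with a median of 1.91 (adjusted p = 0.281 with an estimated correlation). Dendritic cell markers had 5 of 11 higher (8 adjusted over the list alone; median 1.60; adjusted p = 0.508 with an estimated correlation). NK and innate lymphoid cell markers had 5 of 15 higher (11 adjusted over the list alone; median 1.56; adjusted p = 0.407 with an estimated correlation). T cell markers had 4 of 16 higher (6 adjusted over the list alone; median 0.71; adjusted p = 0.564 with an estimated correlation). These 4 lists and the mast cell list were called by camera with its preset correlation. B cell markers had 2 of 13 lower, Cd79b and Pax5 (5 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.00253, and adjusted p = 0.516 with an estimated correlation). Their medians relative to the DSS mean were -0.0017, -0.42 and -0.45 in DSSFEV replicates 1, 2 and 3.

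The libraries were unequal in spread. The biological coefficient of variation was 2.39% among the DSS libraries and 26.2% among the DSSFEV libraries. Between DSS libraries 0.337% to 1.13% of genes differed in a chi-square test of their counts, against 35.2% to 52.9% between DSSFEV libraries. Between DSSFEV replicate 2 and the DSS libraries 30.2% to 31.3% differed, fewer than between it and either other DSSFEV library. In DSSFEV replicate 2 the median log2 difference from the DSS mean was -0.08 for T cell markers and -0.36 for MHC class II genes, but 1.21 for matrix genes and 1.497 for macrophage and monocyte markers. The series design counts 3 saline-treated donors, but no sample label ties a library to an animal, so p-values measure the spread between these libraries, which may be technical.

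**Figure D3:**
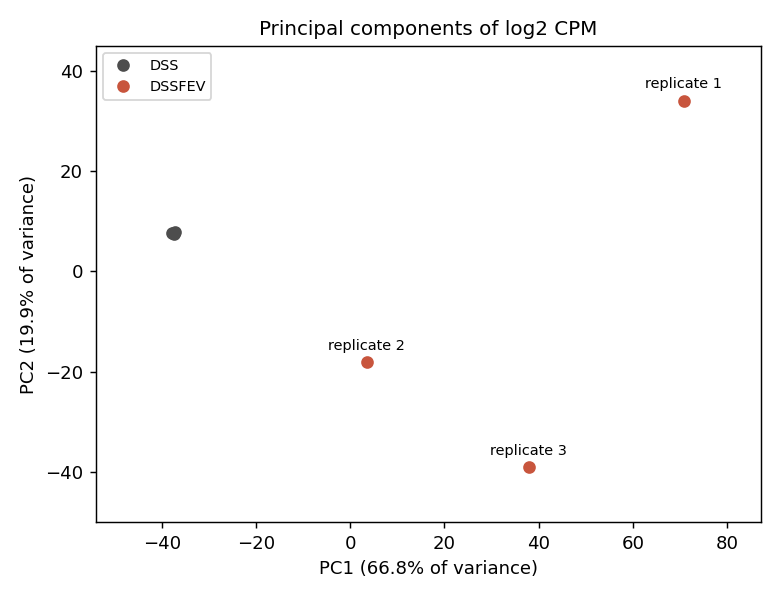
First and second principal components of log2 CPM over tested genes (horizontal 66.8% and vertical 19.9% of variance), points being libraries. The 3 DSS libraries overlap at about -37.1 to -37.7 on the horizontal axis, while DSSFEV replicates 1, 2 and 3 lie at 70.8, 3.53 and 37.9.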

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

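The DSS libraries summed as 1 and the thinning were chosen after seeing the data. Of 145 named genes, 114 passed the threshold, and 0 of those reversed under any setting run. The groups did not overlap in any called gene (1261 higher and 255 lower), so a change of sign was hardly possible. The call was lost by 114 with the DSS libraries summed as 1, by 100, 98 and 100 without DSS replicates 1, 2 and 3, by 58 without DSSFEV replicate 3, 58 with the replicate block, 49 with limma-voom, and 37 and 18 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), and by at most 6 under each other setting. Of the 31 not passing, 13 were gained with DESeq2, 13 and 16 without DSSFEV replicates 1 and 2, and at most 2 elsewhere. Lost calls with the DSS libraries summed or 1 of them left out came with larger errors (median error 1.81 and 1.25 to 1.26 fold). Their folds kept about the same size, as they had to with DSS libraries this alike. The count of 1516 genes moved to 2582 with DESeq2, 692 with limma-voom, 446 with the replicate block, 869 with limma on log2(FPKM + 1), 0 with the DSS libraries summed as 1 (unadjusted p under 0.05 in 1093 with edgeR) and 936 with at least a 2-fold change, and ranged from 81 to 4122 without 1 library. Genes higher (1261) moved to 2023, 573, 437, 765 and 0 under the first 5 of these settings and ranged from 78 to 2667 without 1 library, and genes lower (255) to 559, 119, 9, 104 and 0, to 154 with the stricter filter, to 146 with limma on log2(FPKM + 0.1), and from 3 to 1455 without 1 library. The share higher was 83.2%, 98% with the block and 64.7% to 97.2% without 1 library. Deviations from the group mean correlated at 0.016, -0.0094 and -0.00014 between same-numbered libraries. The DSS libraries differ by little more than counting, so these values cannot show whether the replicate numbers pair samples. The block leaves fewer residual degrees of freedom, which can lower the count with no change in the effect. Whether a weaker effect also took part was not tested.

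Lists past the threshold (23) fell to 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 10 with fry, and stayed at 22 to 25 elsewhere. With an estimated correlation the adjusted p was 0.672 for oxidative phosphorylation, 0.508 for the tricarboxylic acid cycle, 0.281 for matrix, 0.407 for TGF-beta, 0.508 for M1-type and 0.281 for M2-type activation. With fry it was 0.21, 0.0644 and 0.151 for oxidative phosphorylation, the tricarboxylic acid cycle and M1-type activation. For matrix, TGF-beta and M2-type activation the fry adjusted p was 0.0142, 0.0436 and 0.0308. Uncalled lists changed direction: glycolysis without DSSFEV replicate 2 (adjusted p 0.0624 to 0.969 without 1 library) and fatty acid oxidation with fry (0.953), the stricter filter (0.822) and without DSSFEV replicate 2 (0.349 to 0.969 without 1 library). Uncalled genes changed sign near 0: Pkm at -0.0036 with the replicate block, -0.0032 with no filter, -0.0038 with limma-voom, and, without DSSFEV replicate 1 or DSS replicate 1, within -0.11 to 0.13 over the left-out libraries; Cpt1a within -0.027 to 0.053, without DSSFEV replicate 3 or DSS replicate 2; Nos2 at -0.033 with the replicate block, -0.022 with limma-voom and, without DSSFEV replicates 1 or 3, within -0.15 to 0.26. The first component (66.8%) held 57.1% with no filter and 65.8% to 77.3% without 1 library. Fewer libraries or fewer genes enter some of these settings by construction; otherwise the cause was not tested.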

Other observations

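Interferon response genes rose in 13 of 26 cases, with 1 lower (21 higher and 1 lower adjusted over the list alone), at a median of 0.82 (camera adjusted p = 1.69e-09, and adjusted p = 0.407 with an estimated correlation). Ifi44 went from 13.0 ± 0.56 to 24.4 ± 1.04 CPM (n = 3 per group). Lysosome and phagocytosis genes were higher in 10 of 24 (15 adjusted over the list alone; median 0.43; adjusted p = 0.407 with an estimated correlation), among them Ctsk, Axl and Msr1. PPAR and lipid handling had 5 higher and 3 lower of 20 (10 and 4 adjusted over the list alone; median 0.37; adjusted p = 0.407 with an estimated correlation); Apoe, a lipid carrier of macrophages, went from 45.8 ± 3.29 to 357 ± 210 CPM, a log2 fold change of 2.96, and of 2.37 without DSSFEV replicate 3. Cholesterol synthesis had 6 of 21 lower (20 adjusted over the list alone; median -0.45; adjusted p = 0.407 with an estimated correlation), among them Mvd and Cyp51. Proliferation had 3 of 24 lower (3 adjusted over the list alone; median -0.28; adjusted p = 0.516 with an estimated correlation), namely Aurkb, Mcm2 and Tyms. The list's medians relative to the DSS mean were 0.09, -0.40 and -0.57 in DSSFEV replicates 1, 2 and 3. In the tight junction and mucus barrier list 1 of 19 fell, Cldn2 (3 adjusted over the list alone; camera adjusted p = 0.00185, and adjusted p = 0.516 with an estimated correlation), and its median of -0.33 and mean of 0.01 differ in sign. Ribosomal proteins had 0 of 36 called with edgeR (0 adjusted over the list alone; median -0.09; camera adjusted p = 0.0141, and adjusted p = 0.752 with an estimated correlation).

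Lists not called by camera were hypoxia (3 higher and 1 lower of 19, the same numbers adjusted over the list alone), the pentose phosphate pathway (1 lower of 7, and 1 adjusted over the list alone), MHC class II presentation (0 of 11 with edgeR, and 0 adjusted over the list alone), plasma cells (2 higher of 9, and 2), smooth muscle (2 higher of 11, and 2), enteric glia (0 of 5, and 0), immediate early genes (5 higher of 20, and 5), heat shock genes (1 higher of 13, and 2 higher and 1 lower) and mitochondrially encoded genes (1 lower of 12, and 0). Median and mean differ in sign for hypoxia (-0.0051 and 0.10), immediate early (-0.10 and 0.15), heat shock (-0.05 and 0.04) and mitochondrially encoded genes (0.03 and -0.01). Erythroid (0 of 4; 4 higher adjusted over the list alone) and adipocyte markers (1 higher of 3; 1 adjusted over the list alone) were too few to test as lists. In an enrichment of the pathway names given in the table, 42 of 317 were over-represented among genes higher in DSSFEV, with cytokine receptor interaction at 76 of 201 genes and ECM-receptor interaction at 35 of 69. Among genes lower in DSSFEV 0 of 317 passed, and 12 had an unadjusted p under 0.05 (hypergeometric test), no more than a share of 0.05 of the 317 would give. The hypergeometric test treats genes as independent, which genes of a pathway need not be. It also starts from the genes called between the groups, so it carries the limits of those calls.

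Every test below except the repeated-library, thinning and germinal centre tests was chosen after its result was seen. The 3 DSS libraries differ by little more than counting. Their coefficient of variation was 9.11% of that among DSSFEV libraries, which describes the pattern and cannot test repeat preparations of 1 RNA sample or pool. The variance averaged 1.69 times counting. Reads of 1 library divided into 3 would leave a value near 1 if each counted read were independent. The counting tool is not given, so that condition could not be checked and the value cannot decide this. Whether the DSS libraries are technical repeats stays open: the series design counts 3 saline-treated donors, and no sample label ties a library to a donor. In all, 3 simulated repeats of 1 DSSFEV library, tested against the other 2 DSSFEV libraries and 1 DSS library, called 3632 genes for replicate 1, 0 for replicate 2 and 71 for replicate 3. The same repeats of DSS replicate 1 against the 3 DSSFEV libraries called 2347 (1720 higher, 627 lower). The bound set beforehand for the DSSFEV repeats, 1 count of at least 1516, was met by DSSFEV replicate 1 alone, which lies apart from the others, and the DSS library brings the group difference into each of these tests, as the DSSFEV libraries do for the repeats of DSS replicate 1, so whether 1 control sample counted 3 times gave the calls stays open. With all libraries thinned to the smallest total, 92.2% of the called genes (1398) were still called, which argues against depth. The real grouping called 1516 genes and the highest of the other splits 0, in 1 of 10 splits, too few for a share under 0.05.

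Higher stromal and immune genes could reflect a lower share of epithelial cells, which would raise every other cell type alike. The medians of 12 other cell type lists instead ranged over 3.11 log2 units, from -0.23 for B cell markers to 2.88 for neutrophil markers (permutation test, 100000 permutations, p = 0.002; genes of a list are not independent). This test over all lists replaced a comparison of the endothelial and B cell lists alone, which had been picked after their medians were seen. That argues against a lower epithelial share as the whole explanation, and leaves open a change in which cells were recovered, which was not tested. The labels name lamina propria monocytes and give no sort, yet epithelial transcripts were abundant in every library (Muc2 at 7474 to 13566 CPM), so the values do not bear out monocytes alone. Exchange of the group names as a whole cannot be told apart from a true rise, as the matrix median of 1.35 would only change sign and no gene marks the treated animals. Matrix RNA was higher in the DSSFEV libraries, while the series title speaks of relief of fibrosis. A biological effect of the vesicles stays open and untested.

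More fibroblasts in the DSSFEV libraries are a candidate explanation for the matrix rise. Matrix genes exceeded 8 fibroblast identity markers (Pdgfra, Pdgfrb, Thy1, Pdpn, Dpt, Gsn, Fap and Twist1) by 0.033 log2 units at the median (exact permutation test, 2-sided, p = 0.786), as that explanation needs, although a p above the threshold does not show that the medians are equal. Of these markers 4 of 8 passed the threshold, Thy1, Gsn, Fap and Twist1 did not, and all belong to the fibroblast list, Pdgfra being at 32.7 ± 1.52 and 92.5 ± 15.8 CPM. Dpt itself codes for a matrix protein, which blurs the comparison. Another set of 10 identity markers, which leaves out Dpt, was tried first and gave 0.095 (permutation test, 2-sided, p = 0.392).

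Among the largest falls, Rgs13, Mybl1, Mef2b and Gcsam are known germinal centre B cell genes, so fewer such cells may be present. The 10 other germinal centre genes, written down before their values were seen, had a median 0.247 log2 units above that of general B cell markers (permutation test, 2-sided, p = 0.0952), opposite to the prediction but within the spread. Of these, Neil1 was lower and Basp1 higher past the threshold. The hypothesis gained no support, and the test stays undecided because Fas, Lmo2 and Basp1 are also expressed by other cells.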
